A study of Mus musculus with 9 samples.

How the data were processed

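Gene expression was measured in BaF3 cells, a mouse haematopoietic line that needs interleukin-3 to grow, after infection with retroviruses carrying BCR-ABL, BCR-RET or FGFR1OP-RET. Infected cells were sorted by the fluorescence of EGFP, per the labels. Each of the 3 groups had 3 Affymetrix MouseGene 1.0 ST arrays, 9 arrays in all, and the groups and replicate numbers were taken from the sample labels. Whether the 3 arrays of a group came from separate infections or cultures is not given in the sources used here, so p-values measure the spread between these arrays, which may be technical. Uninfected BaF3 cells and cells with the empty vector were not analysed here, so every difference is between fusions and none is against cells without a fusion.

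The authors deposited 1 log2 value per probe set and array, made by gene-level RMA (background correction, quantile normalization and a robust summary of the probes) in Affymetrix Expression Console, per the submitters' processing notes. The software version, the annotation and the genome build are not given in the sources used here, so no coordinates are printed. The deposited log2 values ran from 2.66 to 14.92, and the medians of the 9 arrays lay between 8.01 and 8.04. RMA makes the distributions of the arrays alike, so a change of most transcripts in 1 direction would not be seen. Some values were repeated exactly, at the up to 5 decimals deposited, and the source of the repeats was not tested. Of the genes tested, 30.1% had the same value on at least 3 arrays, and 872 genes had a single value on all 3 arrays of some group, for which the SD of that group is 0. Detection calls and scanner intensities were not used here, and the precision of each value is limited by the number of arrays.

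Of the 35557 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12147 had none. Probe sets with several symbols or none were left out of the main tests. Symbols were matched through Entrez identifiers to a mouse reference gene table of assembly GRCm38.p6, used for names alone, which changed no symbol; 91 identifiers were not in it. For 999 genes with several probe sets, the probe set with the highest mean over the 9 arrays was kept, leaving 19938 genes.

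The 3 pairwise comparisons of the fusions were fitted on the deposited log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a mean for each group and all 9 arrays sharing 1 estimate of the spread. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Unless stated otherwise, an adjusted p is from this test, ± is the SD of 3 arrays and SE is the standard error of a log2 difference. The median SE over all genes was 0.07. On simulated data with 200 of 19938 genes changed, the same test recovered 74%, 66% and 76.5% of changes of 0.5 on the log2 scale, for BCR-RET against BCR-ABL, FGFR1OP-RET against BCR-ABL and BCR-RET against FGFR1OP-RET. For changes of 1 it recovered 97%, 98% and 98%, in the same order. False calls made up between 2.97% and 6.33% of the calls. Each share comes from 1 draw in the same setting, so differences between the comparisons do not measure a difference in power. The simulated noise was independent for each gene and array, without deviations shared between arrays or repeated values, so these shares may not hold for the real data.

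Before the data were examined, 32 gene lists were fixed, 11 of them markers of blood cell types or stroma and the rest pathways and gene families. The lists named 633 genes, of which 579 were measured and 31 stood in several lists. The 31 lists with at least 5 measured genes were tested with camera in limma, which compares a list with all other genes at a preset correlation of 0.01, with Benjamini-Hochberg adjustment within each comparison. Camera with an estimated correlation and fry were run beside it. Members past the threshold are given over all genes and adjusted over the list alone.

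The genes named in the text follow a rule also fixed before the data were examined. It takes, per comparison, the 8 highest and 8 lowest log2 differences among genes past the threshold whose group ranges do not overlap, without predicted genes and clones. It adds up to 4 members past the threshold from each list that passed camera or had at least 3 such members, up to 8 from the monocyte and macrophage list, and the fusion partner genes Ret, Bcr, Abl1 and Cep43 (the current symbol of Fgfr1op). Genes from the first part therefore had all 3 arrays of one group above all 3 of the other. The rule named 32, 40 and 38 genes, counting a gene once in a comparison.

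Replicate numbers in the labels are shared by the groups. Deviations from the group means correlated between BCR-RET and BCR-ABL arrays of the same number with r of 0.617, 0.155 and 0.367 for numbers 1, 2 and 3, across genes, which are not independent replicates. All 3 exceeded the limit of 0.1 set for treating numbers as pairs, so blocked values are given for that comparison where they change a call. The pairing comes from the data, since the labels do not say what a number marks.

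For genes passing in both comparisons against BCR-ABL, which share the BCR-ABL arrays, unchanged groups were simulated against shared controls in 100 draws. Alternatives were an intensity trend with robust priors, only the 6 arrays compared, array weights, a filter on dim genes, quantile normalization again, median centring, all probe sets, a limit on the log2 difference, the replicate block and leaving out each array in turn. A fit on the arrays numbered 2 and 3 alone was added after seeing the data. Figures were drawn with matplotlib.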

Results

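The data set held 9 arrays of BaF3 cells, 3 for each of the fusion tyrosine kinases BCR-ABL, BCR-RET and FGFR1OP-RET. BCR-ABL is the fusion kinase of chronic myeloid leukaemia. BCR-RET and FGFR1OP-RET join the kinase RET to a partner protein, and the series title links them to chronic myelomonocytic leukaemia and to differentiation along the monocyte line. The 3 pairwise comparisons ask how the RET fusions differ from BCR-ABL and from each other, and a list of monocyte and macrophage genes addressed the monocyte line. Correlations between arrays over all probe sets were 0.993 to 0.996 within groups and 0.990 to 0.996 between groups.

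The genes that contribute to the fusions were read first. Abl1 (probe set 10471201) was at 11.19 ± 0.07 in BCR-ABL cells, 10.73 ± 0.11 in BCR-RET cells and 10.94 ± 0.07 in FGFR1OP-RET cells (log2, n = 3). It fell in BCR-RET against BCR-ABL by 0.46 (SE 0.07, adjusted p = 0.0219; 0.127 without BCR-ABL replicate 2), whereas the difference of FGFR1OP-RET from BCR-ABL, -0.25, did not pass (adjusted p = 0.207). Ret (probe set 10547227) lay at 7.89 ± 0.09, 8.03 ± 0.04 and 8.06 ± 0.05 in the same order, and neither RET fusion differed from BCR-ABL past the threshold (adjusted p = 0.417 and 0.329). Bcr (probe set 10364009) had means of 10.84, 10.70 and 10.41, and Cep43 (probe set 10441620) had means of 10.16, 10.13 and 10.23, with no comparison past the threshold. The labels do not give the species or the part of each gene in the constructs, so these mouse probe sets may not see the fusion transcripts and do not check the labels.

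Cells with BCR-RET expressed more Pdcd1, Casp4 and Tnfrsf9, and more of several interferon response and cytokine genes, than cells with BCR-ABL. Pdcd1, an inhibitory receptor of activated lymphocytes, rose 4.24-fold, from 7.22 ± 0.07 to 9.30 ± 0.14 (log2 difference 2.08, SE 0.07, n = 3, adjusted p = 2.86e-06). Casp4, an inflammatory caspase, rose by 1.51 (SE 0.19, adjusted p = 0.00931) and Tnfrsf9, a costimulatory receptor, by 1.17 (SE 0.12, adjusted p = 0.00326). Tmem119, which encodes a membrane protein, fell by 1.46 (SE 0.08, adjusted p = 8.54e-05), and the cadherin gene Cdh17 fell by 1.10 (SE 0.14, adjusted p = 0.0101). In all, 117 of 19938 genes passed, 74 higher and 43 lower in BCR-RET, and 13 of them differed by at least 1 on the log2 scale.

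Other genes at the top of this comparison were the mucin gene Muc13 (1.12) and the galectin gene Lgals9 (1.10). At the lower end were Mamdc2 (-1.04), the pyruvate dehydrogenase phosphatase gene Pdp1 (-0.99), the complement gene Cfp (-0.93), the granzyme gene Gzmc (-0.86) and the endoplasmic reticulum peptidase gene Ermp1 (-0.80).

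Of 24 measured interferon response genes, 4 rose and none fell in BCR-RET against BCR-ABL. Adjusted over the list alone 16 rose, and all 24 had a difference above 0. The 4 were the chemokine gene Cxcl10 (1.16, SE 0.11), Ifit1 (1.05, SE 0.15), Oasl2 (0.76, SE 0.11) and Ifit3 (0.69, SE 0.09). The list median was 0.35 (camera adjusted p = 6.91e-17; adjusted p = 0.124 with an estimated correlation). Among 27 cytokines and chemokines 4 rose, namely Cxcl10, Il6 (1.07), Osm (0.82) and Ccl17 (0.52), with 6 adjusted over the list alone (camera adjusted p = 0.00425; adjusted p = 0.124 with an estimated correlation). Il6 was also the member that rose among 18 NF-kB targets, whose median was 0.17 (camera adjusted p = 3.64e-06; adjusted p = 0.124 with an estimated correlation; 7 adjusted over the list alone). Csf2rb (0.72), the beta chain shared by the interleukin-3, interleukin-5 and GM-CSF receptors, its close relative Csf2rb2 (0.90), specific to interleukin-3, and Il2ra (0.80) rose among 25 cytokine receptors. Cross-hybridisation between the probe sets of Csf2rb and Csf2rb2 was not tested. Adjusted over the list alone 4 rose and 1 fell. That list passed narrowly (camera adjusted p = 0.0497; adjusted p = 0.0904 with the replicate number as a block and 0.429 with an estimated correlation). Its call ended without BCR-ABL replicates 1 and 2 (adjusted p = 0.0813 and 0.0789), BCR-RET replicate 2 (0.119) and FGFR1OP-RET replicates 1 and 2 (0.0631 and 0.0686).

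Among 11 erythroid genes the transcription factor genes Gata1 (0.75, SE 0.08) and Klf1 (0.47, SE 0.08) rose. Adjusted over the list alone 4 rose, and the list median was 0.15 (camera adjusted p = 0.00105; adjusted p = 0.124 with an estimated correlation). The 21 granulocyte genes had a median of 0.27 and none passed over all genes, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.0e-04; adjusted p = 0.429 with an estimated correlation). The 6 eosinophil genes had a median of 0.26, none passed over all genes and 3 rose adjusted over the list alone (camera adjusted p = 0.0474; adjusted p = 0.429 with an estimated correlation). The eosinophil call ended without BCR-ABL replicates 1 and 2 (adjusted p = 0.0813 and 0.127), BCR-RET replicates 2 and 3 (0.119 and 0.0830) and FGFR1OP-RET replicates 1 and 2 (0.0580 and 0.0686). In the monocyte and macrophage list Cybb, a subunit of the phagocyte oxidase, rose by 0.99 and Emilin2 fell by 0.43, and the 32 measured genes as a list did not pass (median 0.08, camera adjusted p = 0.188; 2 higher and 1 lower adjusted over the list alone).

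Hbegf (-0.80), a growth factor of the EGF family, and the transcription factor gene Etv5 (-0.55) fell among 24 ERK targets, and 5 fell adjusted over the list alone. The ERK list passed with a lower direction and a mean of -0.07, while its median was 0.01 (camera adjusted p = 0.0474; adjusted p = 0.631 with an estimated correlation). It did not pass without BCR-ABL replicate 1 (adjusted p = 0.213), BCR-RET replicates 2 and 3 (0.172 and 0.111) or FGFR1OP-RET replicates 1 and 2 (0.0580 and 0.0686). None of 26 MYC and ribosome biogenesis genes passed, over all genes or adjusted over the list alone, and the list median was -0.04 (camera adjusted p = 0.0103; adjusted p = 0.618 with an estimated correlation; 0.0730 without BCR-ABL replicate 2). None of 21 mitosis genes passed in either way, with a list median of -0.05 (camera adjusted p = 0.0474; adjusted p = 0.0824 with the replicate number as a block and 0.643 with an estimated correlation). The mitosis call ended without BCR-ABL replicate 2 (adjusted p = 0.188), BCR-RET replicates 1 and 3 (0.361 and 0.0745) and FGFR1OP-RET replicates 1 and 3 (0.0524 and 0.0627). The 21 B lymphoid genes and the 18 mast cell and basophil genes had no member past the threshold (camera adjusted p = 0.149 and 0.672).

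With the replicate number as a block, 362 genes passed in BCR-RET against BCR-ABL, 237 higher and 125 lower, among them all 117. The count was 46, 28 and 51 without BCR-ABL replicates 1, 2 and 3, and 57 and 34 without BCR-RET replicates 2 and 3. Of 29 named calls, Pdcd1, Tnfrsf9, Cxcl10, Muc13, Il6, Tmem119, Pdp1, Gzmc, Ermp1, Hbegf, Gata1, Osm, Csf2rb2 and Csf2rb held without each array in turn. The other 15 reached highest adjusted p values of 0.0566 to 0.209, for Ifit1 and Cdh17 without BCR-RET replicate 3 and for the rest without BCR-ABL replicate 2. Most of the 15 did not hang on a single array. Leaving out any 1 of 8 arrays ended the call of Klf1, any 1 of 6 that of Lgals9 and any 1 of 5 those of Mamdc2, Cfp and Abl1.

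Cells with FGFR1OP-RET expressed more of several interferon response, granulocyte and monocyte genes than cells with BCR-ABL. Oas2, an interferon-induced synthetase of the antiviral response, rose 3.85-fold, from 8.82 ± 0.10 to 10.76 ± 0.27 (log2 difference 1.94, SE 0.14, n = 3, adjusted p = 5.07e-04). The neutrophil granule genes Mpo (1.55, SE 0.28, adjusted p = 0.0347) and Prtn3 (1.27, SE 0.13, adjusted p = 0.00234) and the monocyte receptor gene Cd14 (1.06, SE 0.16, adjusted p = 0.0146) rose. Odf3b fell by 1.73 (SE 0.20, adjusted p = 0.00403) and Havcr2, an inhibitory receptor of T cells, fell by 1.37 (SE 0.20, adjusted p = 0.0113). In all, 203 genes passed, 157 higher and 46 lower in FGFR1OP-RET, and 30 differed by at least 1 on the log2 scale.

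Further genes at the top were Slfn4 (1.51), the chemokine receptor gene Ccr1 (1.30) and Oas3 (1.28). The aldo-keto reductase genes Akr1c12 (-1.17) and Akr1c13 (-0.96), Gzmc (-1.11), Ryk (-1.03), and the kinase gene Pim2 (-0.99) fell, and the chemokine receptor gene Ccr4 was 2.01-fold lower. Akr1c12 and Akr1c13 are close relatives, and cross-hybridisation between their probe sets was not tested.

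Of 24 interferon response genes 11 rose and none fell in FGFR1OP-RET against BCR-ABL, with 22 higher adjusted over the list alone and a median of 0.49. After Oas2, the largest were the transcription factor gene Irf7 (1.25, SE 0.12), Usp18 (1.18, SE 0.15) and Oasl2 (1.13, SE 0.11). This list had the lowest p of the 31 tested (camera adjusted p = 1.77e-30; adjusted p = 0.0600 with an estimated correlation).

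Among 21 granulocyte genes 5 rose and none fell, and 12 rose adjusted over the list alone. They included Mpo, the collagenase gene Mmp8 (1.33), Prtn3 and S100a9 (0.96, from 12.21 ± 0.07 to 13.17 ± 0.15). The list median was 0.47 (camera adjusted p = 1.03e-12; adjusted p = 0.0829 with an estimated correlation). The monocyte and macrophage list had 4 of 32 genes higher and none lower, namely Cd14, the perforin-like gene Mpeg1 (1.01), the Fc receptor gene Fcgr1 (0.57) and Ifi30 (0.46). Its median was 0.14, with 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.07e-07; adjusted p = 0.117 with an estimated correlation). The erythroid genes Gata1 (0.45) and Nfe2 (0.39) rose among 11, with 4 adjusted over the list alone (camera adjusted p = 0.00657; adjusted p = 0.158 with an estimated correlation). Without FGFR1OP-RET replicate 1 that list had an adjusted p of 0.0519. Among 17 T and NK genes the granzyme gene Gzmb fell by 0.35 and 2 fell adjusted over the list alone (camera adjusted p = 0.0171; adjusted p = 0.126 with an estimated correlation; 0.0700 without BCR-ABL replicate 1).

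Ccl3 (1.26), Ccl9 (1.19) and Cxcl2 (0.59) with the cytokine gene Osm (0.56) made up the 4 of 27 cytokines and chemokines past the threshold. Adjusted over the list alone 6 rose (camera adjusted p = 3.07e-04; adjusted p = 0.0600 with an estimated correlation). Ccl3 and Cxcl2 were also the 2 of 18 NF-kB targets that rose, with 6 adjusted over the list alone (camera adjusted p = 3.31e-05; adjusted p = 0.0829 with an estimated correlation). Ccr1, Csf2rb (0.69) and Csf2rb2 (0.56) rose among 25 cytokine receptors, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.00657; adjusted p = 0.171 with an estimated correlation; 0.0995 without FGFR1OP-RET replicate 3). Of 24 adhesion molecules the integrin genes Itgb2 (0.58), Itgb3 (0.50) and Itgal (0.37) rose and Itgav fell by 0.54. Itgb3 had 1 repeated value, 8.96, on all 3 FGFR1OP-RET arrays, and this SD of 0 lowers the spread behind its call. The adhesion list did not pass (camera adjusted p = 0.104; 7 higher and 2 lower adjusted over the list alone).

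Lists with a lower direction and no member past the threshold over all genes were mitosis (21 genes, median -0.09, camera adjusted p = 0.00298), oxidative phosphorylation (19 genes, median -0.09, adjusted p = 0.00319), ATF4 amino acid stress (30 genes, median -0.06, adjusted p = 0.0219) and the unfolded protein response (18 genes, median -0.05, adjusted p = 0.0472). In the same order, these had an adjusted p = 0.457, 0.457, 0.171 and 0.558 with an estimated correlation. Adjusted over the list alone, 2 genes of the unfolded protein response fell and none of the other 3 lists did. Mitosis had an adjusted p of 0.107 without FGFR1OP-RET replicate 2. Amino acid stress had 0.0564 without BCR-ABL replicate 2 and 0.0509 and 0.239 without FGFR1OP-RET replicates 2 and 3. The unfolded protein response had 0.0564 and 0.337 without BCR-ABL replicates 2 and 3, 0.0524 and 0.0612 without BCR-RET replicates 2 and 3, and 0.0519 and 0.217 without FGFR1OP-RET replicates 1 and 2.

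Without BCR-ABL replicates 1, 2 and 3 the count for FGFR1OP-RET against BCR-ABL was 100, 70 and 95, and it was 134 without BCR-RET replicate 2 and 106 without FGFR1OP-RET replicate 2. Of 36 named calls, Oas2, Oas3, Prtn3, Odf3b, Akr1c12, Gzmc, Ryk, Ccr4, Pim2, Irf7, Oasl2, Osm, Csf2rb and Itgav held without each array in turn. The other 22 reached highest adjusted p values of 0.0506 (Usp18, without BCR-ABL replicate 2) to 0.208 (Ccl3, without FGFR1OP-RET replicate 2). No monocyte and macrophage call of this comparison held, since Cd14, Mpeg1, Fcgr1 and Ifi30 were all among the 22. So were the granulocyte genes Mpo, Mmp8 and S100a9, while Prtn3 held. The 2 lists themselves passed camera at its preset correlation without each array in turn. Among the 22, leaving out any 1 of 8 arrays ended the call of Itgal, and any 1 of 7 those of Mpo, Fcgr1 and Gata1.

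**Figure D1:**
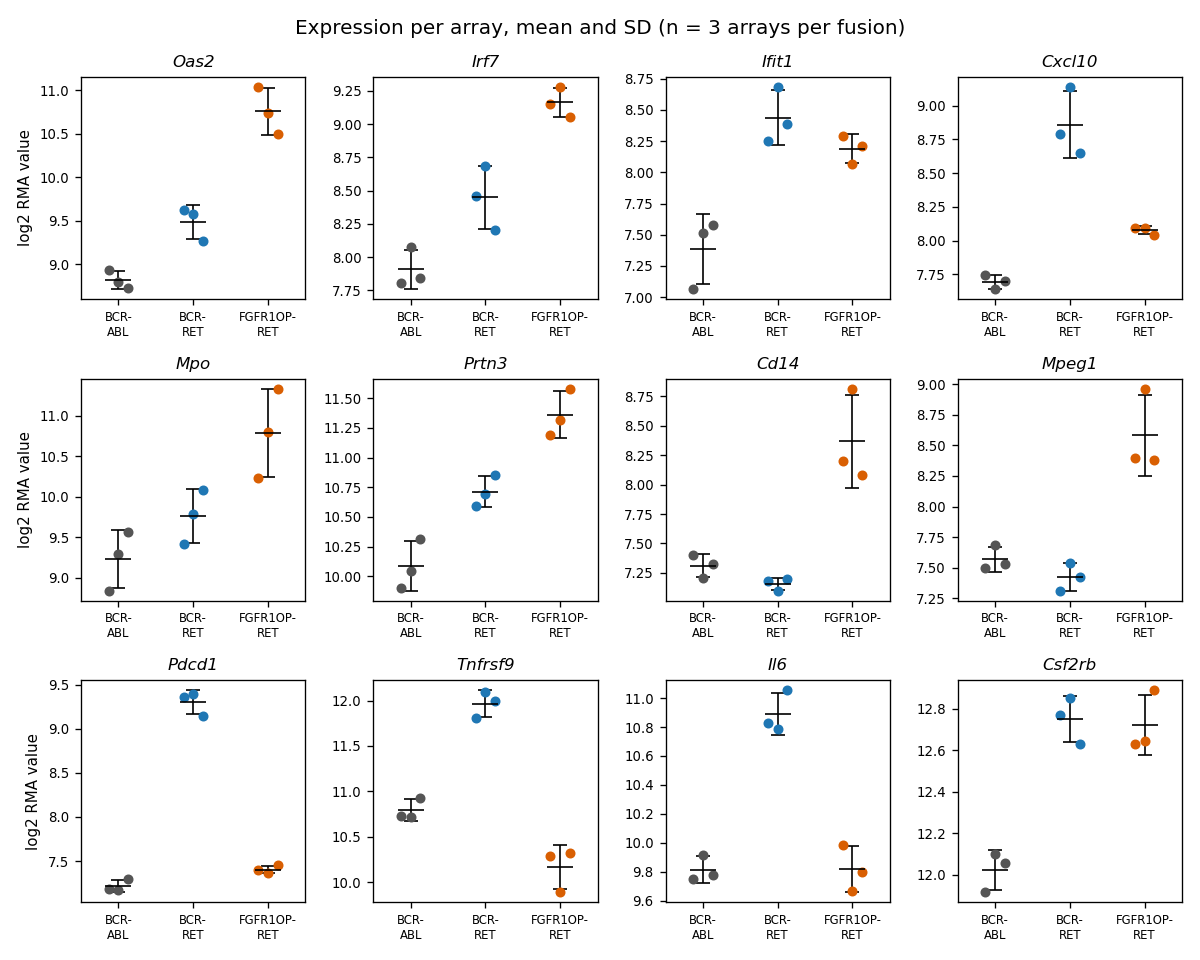
Log2 RMA value (vertical axis) of 12 genes on each array, by fusion, with points for the 3 arrays of a group and a bar for the mean with its SD; each panel has its own vertical scale, which does not start at 0. Pdcd1 was at 9.30 in BCR-RET cells against 7.22 and 7.40 in BCR-ABL and FGFR1OP-RET cells, while Cd14 was at 8.37 in FGFR1OP-RET cells against 7.31 and 7.16 in BCR-ABL and BCR-RET cells.

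The comparisons against BCR-ABL shared 34 genes that changed alike, 20 higher and 14 lower in both RET fusions. Higher in both were the interferon response genes Ifit1 (1.05 and 0.80 for BCR-RET and FGFR1OP-RET) and Oasl2 (0.76 and 1.13), and the cytokine gene Osm (0.82 and 0.56). So were the receptor genes Csf2rb (0.72 and 0.69) and Csf2rb2 (0.90 and 0.56), the integrin gene Itgb3 (0.82 and 0.50, with an SD of 0 in FGFR1OP-RET) and Gata1 (0.75 and 0.45). Lower in both were Tmem119 (-1.46 and -0.87), Gzmc (-0.86 and -1.11), Hbegf (-0.80 and -0.66), Ermp1 (-0.80 and -0.58), Etv5 (-0.55 and -0.35) and Itgav (-0.37 and -0.54). Of the 34, 5 also differed between the RET fusions. Another 3 genes changed in opposite directions.

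Simulated unchanged groups that share the BCR-ABL arrays gave 0 genes alike in each of 100 draws, but at most 1 gene passed per comparison in any draw, so that 0 sets no measure for the 34. Independent lists of these sizes, without shared arrays, would have 0.58 higher and 0.099 lower genes in common. The log2 differences of the 2 comparisons correlated with r = 0.385 across genes, which are not independent replicates, against 0.5 for unchanged groups. Their covariance was 0.00708 against 0.00461 simulated, a difference of 0.00248, and 62.1% of genes had the same sign against 66.7% simulated. With 3 BCR-ABL arrays the controls could not be split into parts of at least 2, so part of the overlap may come from the shared arrays. With another fusion as the shared group, counted after seeing the data, 46 genes changed alike against BCR-RET and 87 against FGFR1OP-RET. Without BCR-ABL replicates 1, 2 and 3 the count was 12, 7 and 14, without BCR-RET replicates 1, 2 and 3 it was 22, 17 and 15, and it was 20 without FGFR1OP-RET replicate 2.

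**Figure D2:**
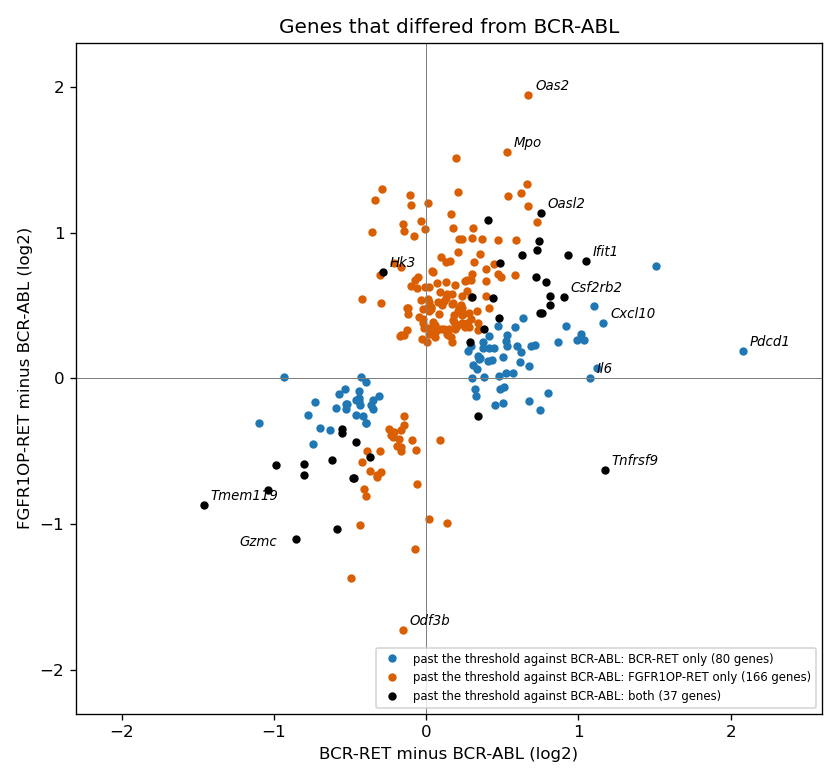
Log2 difference of BCR-RET (horizontal axis) and FGFR1OP-RET (vertical axis) from BCR-ABL for the 283 genes past the threshold in at least 1 of the 2 comparisons, 1 point per gene. Black points are the 37 genes past it in both, 34 of which lie in the quadrants of equal sign. Blue points are 80 genes past it for BCR-RET and orange points 166 genes past it for FGFR1OP-RET, and membership in a single set does not show a difference between the RET fusions.

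Between the RET fusions, cells with BCR-RET expressed more Pdcd1 and Tnfrsf9 and less Ccr1, Trem1 and Mmp9 than cells with FGFR1OP-RET. Pdcd1 was 3.73-fold higher with BCR-RET (log2 difference 1.90, SE 0.07, n = 3, adjusted p = 6.88e-06). Tnfrsf9 was at 11.97 ± 0.14 with BCR-RET and 10.17 ± 0.24 with FGFR1OP-RET (1.80, SE 0.12, adjusted p = 2.68e-04). Ccr1 was lower with BCR-RET by a log2 difference of -1.59 (SE 0.20, adjusted p = 0.00591), the receptor gene Trem1 by -1.49 (SE 0.24, adjusted p = 0.0216) and the gelatinase gene Mmp9 by -1.44 (SE 0.18, adjusted p = 0.00591). In all, 265 genes passed, 95 higher and 170 lower with BCR-RET, and 32 differed by at least 1 on the log2 scale. A fit on the 6 arrays compared passed 34 genes. The full fit also draws its spread from the BCR-ABL arrays. Their median correlations within the group were 0.9953 to 0.9961, against 0.9936 to 0.995 in BCR-RET and 0.9929 to 0.9933 in FGFR1OP-RET. The SEs and the count of 265 may thus be too favourable for this comparison, and the cause of the drop was not tested. With the replicate number as a block 1135 passed, 561 higher and 574 lower, so the lean to lower values was not kept in that fit. Number 2 had an r of -0.152 between the RET fusions, below the pairing limit of 0.1, so these arrays were not treated as pairs.

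Also higher with BCR-RET were Odf3b (1.58), the carbonic anhydrase gene Car13 (1.29), Ctla2a (1.18) and Akr1c12 (1.10). Lower were Cstdc6 (-1.56), Lilr4b (-1.38), Lilrb4a (-1.36) and the myeloid lectin gene Clec5a (-1.36). Lilr4b and Lilrb4a are close relatives, as are members of the family of Cstdc6, and cross-hybridisation between their probe sets was not tested.

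Of 24 interferon response genes 4 were lower and 2 higher with BCR-RET than with FGFR1OP-RET, with 13 lower and 3 higher adjusted over the list alone and a median of -0.25. Oas2 (-1.27), Ddx58 (-0.72) and Irf7 (-0.71) were among the lower members and Cxcl10 (0.78) among the higher (camera adjusted p = 4.61e-05; adjusted p = 0.557 with an estimated correlation). In the granulocyte list Mmp9, the transcription factor gene Cebpe (-0.73) and Prtn3 (-0.65) were lower among 21 genes, and adjusted over the list alone 7 were lower and 3 higher (median -0.18, camera adjusted p = 0.00178; adjusted p = 0.557 with an estimated correlation). Cd14 (-1.21), Mpeg1 (-1.16) and the Fc receptor gene Fcgr3 (-0.99) were lower and Cybb (0.73) higher among 32 monocyte and macrophage genes, with 9 lower and 1 higher adjusted over the list alone. The monocyte and macrophage median was -0.07 (camera adjusted p = 0.00299; adjusted p = 0.557 with an estimated correlation; 0.0551 without BCR-RET replicate 1).

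The 19 oxidative phosphorylation genes had a median of 0.14 with none past the threshold over all genes and 1 higher adjusted over the list alone (camera adjusted p = 0.00256; adjusted p = 0.557 with an estimated correlation). Among 17 T and NK genes the adaptor gene Lat (0.32) was higher, with 2 adjusted over the list alone and a median of 0.09 (camera adjusted p = 0.00823; adjusted p = 0.419 with an estimated correlation). Among 21 lysosome genes the channel gene Mcoln1 (-0.26) was lower, with 2 adjusted over the list alone (camera adjusted p = 0.0182; adjusted p = 0.557 with an estimated correlation; 0.207 without BCR-RET replicate 1 and 0.232 without FGFR1OP-RET replicate 3). Lists that did not pass still held changed members. The JAK-STAT targets Pim2 (1.13), Il2ra (0.90) and Socs1 (0.37) were higher with BCR-RET (3 of 18, camera adjusted p = 0.139; 5 adjusted over the list alone). Of 14 stem and progenitor genes Lmo2 (-0.97) and Myb (-0.32) were lower and Slamf1 (0.62) higher (camera adjusted p = 0.304; the same counts adjusted over the list alone). The cytokine genes Il6 (1.07) and Cxcl10 were higher and the chemokine genes Ccl3 (-1.37) and Ccl9 (-1.28) lower, in a list of 27 with 3 higher and 2 lower (camera adjusted p = 0.943; 4 and 3 adjusted over the list alone).

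Without BCR-ABL replicates 1, 2 and 3 the count between the RET fusions was 153, 122 and 145, without BCR-RET replicates 2 and 3 it was 90 and 100, and without FGFR1OP-RET replicates 1 and 2 it was 171 and 86. Of 34 named calls, Pdcd1, Tnfrsf9, Odf3b, Ctla2a, Pim2, Il6, Ccr1, Cstdc6, Mmp9, Lilrb4a, Cd14, Mpeg1, Cebpe, Lmo2, Il2ra, Oas2 and Ddx58 held without each array in turn. The other 17 reached highest adjusted p values of 0.0501 (Cxcl10, without FGFR1OP-RET replicate 2) to 0.179 (Cybb, without BCR-RET replicate 3). Among the 17, leaving out any 1 of the 9 arrays ended the calls of Socs1 and Mcoln1. For Fcgr3, Cybb, Prtn3, Lat and Myb, any 1 of 8 arrays did so.

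**Figure D3:**
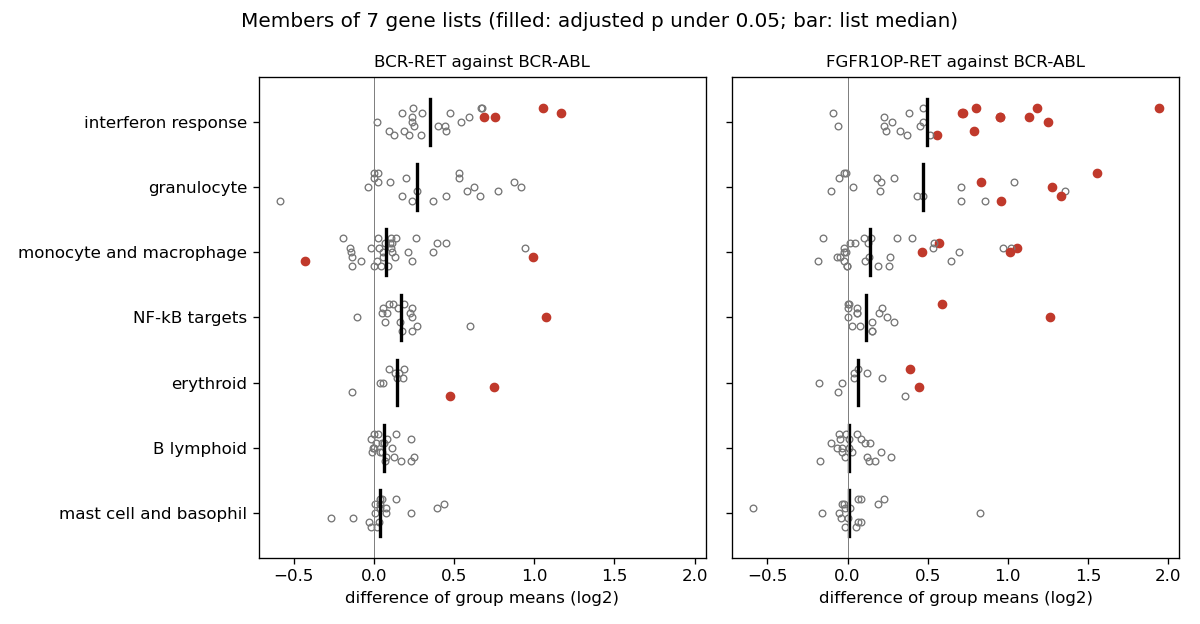
Log2 difference from BCR-ABL (horizontal axis) of each measured member of 7 gene lists, for BCR-RET (left) and FGFR1OP-RET (right); filled points passed the threshold over all genes, open points did not, and black bars are list medians. The interferon response medians were 0.35 and 0.49 and the granulocyte medians 0.27 and 0.47, while the B lymphoid medians were 0.06 and 0.01.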

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

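The tests of mature neutrophil transcripts, of macrophage transcripts, of random lists matched on level and of splits within array numbers were chosen after the results were seen; the other tests in this part were not. Single arrays far from the others of their group were not tested for in groups of 3.

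Tnfrsf9, Hk3 and Nudt7 changed in opposite directions in the RET fusions against BCR-ABL, and the difference between the RET fusions itself passed. Tnfrsf9 was at 1.17 for BCR-RET and -0.63 for FGFR1OP-RET, a difference of 1.80. Hk3, a hexokinase gene, was at -0.28 and 0.73, a difference of -1.01, and Nudt7 at 0.34 and -0.26, a difference of 0.59. Hk3 and Nudt7 lie outside the naming rule and were chosen after their values were seen. Lists that differed between the RET fusions by camera were interferon response (adjusted p = 4.61e-05), granulocyte (0.00178), oxidative phosphorylation (0.00256), monocyte and macrophage (0.00299), T and NK (0.00823) and lysosome (0.0182), none of which passed with an estimated correlation. Of these lists, T and NK alone passed with fry (adjusted p = 0.00902). Of 13768 probe sets without a single gene symbol, which the comparisons did not use, 2 passed for BCR-RET against BCR-ABL, 1 for FGFR1OP-RET against BCR-ABL and 1 between the RET fusions.

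The interferon response list was shifted to higher values in both RET fusion groups against BCR-ABL, with 4 and 11 of 24 members past the threshold and adjusted p = 0.124 and 0.0600 with an estimated correlation. The lowest of the 6 within-number medians was 0.277, which decides nothing about deviations shared by a number, since each number occurs once in every group. A shift common to genes of the same brightness is argued against by 10000 random lists matched on level, among which the list's medians stood at percentile 100 in both comparisons. The random genes were drawn independently, while list members are correlated, and the list was taken up after its result was seen. The percentile therefore speaks to brightness alone and is no further support for the shift. A hypothesis left open is that the RET fusions raise these genes, or BCR-ABL lowers them, but differences in virus exposure or culture between infections may do the same and went untested.

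The granulocyte and monocyte lists were shifted to higher values in FGFR1OP-RET against BCR-ABL, with 5 of 21 and 4 of 32 members past the threshold and adjusted p = 0.0829 and 0.117 with an estimated correlation. The lowest within-number median of both lists, 0.154, decides nothing either, for the same reason. The 8 abundant neutrophil transcripts had a median of 0.38 (95% bootstrap interval 0.032 to 0.957) and the 10 macrophage transcripts 0.1 (0.0162 to 0.571). These intervals resample the genes of a set, not the arrays, so they do not measure the spread between arrays. Both intervals reach 0.506, 0.5 times the median of 1.01 of the 9 called members, so this test cannot tell admixed mature cells from a change within the cells. The 9 were picked because they passed, which raises that limit. The cells were a line sorted by EGFP, with no tissue in the design that would supply mature cells. S100a8 and Ngp were already at 12.53 and 12.71 in BCR-ABL cells, and Camp and Csf1r were at 7.47 and 7.09 in FGFR1OP-RET cells with no change past the threshold. Of the 18 transcripts 14 also stand in the fixed lists, and S100a9 and Mpeg1 are among the 9 called members. The macrophage transcripts outside the lists, C1qa, C1qb, C1qc and Apoe, changed by -0.158, -0.005, 0.051 and 0.097, none past the threshold. A change of myeloid differentiation state with FGFR1OP-RET remains a hypothesis.

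The 265 genes that differed between the RET fusions were set against other splits. In a fit on the 6 arrays alone the real split gave 34 genes, and 2 of 10 splits gave as many: BCR-RET replicate 1 with FGFR1OP-RET replicates 1 and 2 against the rest gave 64. That split follows the main axis of variation within groups, so a structure of the samples other than the fusion is present. With the replicate number as a block, although these arrays were not treated as pairs, 1135 genes passed, 561 higher and 574 lower with BCR-RET, against 95 and 170 without it. For this comparison 10 splits are too few for a share under 0.05.

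Against BCR-ABL, 1 of 10 splits gave as many as the real 56 genes for BCR-RET and 1 of 10 as many as the real 94 for FGFR1OP-RET, and the highest other split gave 0 in limma in both. At an unadjusted p under 0.05 the real splits had 2425 and 1881 genes and the other splits up to 1796 and 3462. For FGFR1OP-RET the split with 3462, BCR-ABL replicate 1 with FGFR1OP-RET replicates 1 and 2 against the rest, thus exceeded the real one in that count. For BCR-RET, the other splits that part all 3 numbered pairs gave 0 as well, and the rest keep a pair on one side. Here too 10 splits are too few for a share under 0.05.

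For the 34 genes alike in both RET fusions, 100 splits of the 9 arrays were drawn without regard to the numbers. The real split alone, 1 of the 100, gave as many, and the highest other gave 9. Of 100 splits that keep 1 array of each number in each group, 3 gave as many. The other 2 of these kept the real groups whole and took another fusion as the shared group, with 46 genes for BCR-RET and 87, the highest other, for FGFR1OP-RET. The count of 34 is therefore not particular to BCR-ABL as the shared group. The highest split that mixed the groups gave 28. With the replicate number as a block the real split gave 118, again 3 of 100 gave as many, and the highest other gave 296, or 69 among splits that mixed the groups. The real split thus gave more genes than any drawn split that mixed the groups, which shows that the arrays differ by group. Whether 34 exceeds the overlap from shared arrays, or from single cultures or infections, cannot be decided, since no split varies these apart from the groups.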

How the results depend on the processing

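The fit on arrays numbered 2 and 3 alone was chosen after seeing the data. Counts below follow the order BCR-RET against BCR-ABL, FGFR1OP-RET against BCR-ABL, BCR-RET against FGFR1OP-RET and alike in both RET fusions, set against 117, 203, 265 and 34. They were 56, 94, 34 and 17 with only the arrays compared, where fewer arrays estimate the spread and the remaining group adds nothing to it. On arrays numbered 2 and 3 alone, with fewer arrays, they were 28, 62, 67 and 6. They were 13, 30, 32 and 0 at an absolute log2 difference of at least 1, by construction, and 362, 576, 1135 and 118 with the replicate block. Array weights gave 293 for the first and 76 for the last, and the cause of these and of the block's counts was not tested. Quantile normalization, median centring, a trend with robust priors, the filter on dim genes and all probe sets kept each count within 1.5 times. Leaving out an array in turn gave 28 to 114, 70 to 185, 86 to 194 and 7 to 32 genes, with fewer arrays in each fit. Lists passing camera numbered 10, 12 and 6 of 31. With an estimated correlation they were 0, 0 and 0 (4, 9 and 1 at an unadjusted p under 0.05), with fry 9, 8 and 3, and without an array 6 to 12, 9 to 12 and 6 to 9. In BCR-RET against BCR-ABL fry lost granulocyte (adjusted p = 0.0619), MYC, ERK and mitosis, and added B lymphoid (0.0446), megakaryocyte and JAK-STAT targets (both 0.0347). In FGFR1OP-RET against BCR-ABL it lost mitosis, oxidative phosphorylation, amino acid stress and the unfolded protein response. Between the RET fusions fry passed T and NK (0.00902), amino acid stress and JAK-STAT targets (both 0.0481) and no other list. The cause of the list differences was not tested. No named call changed sign in any alternative run that tested it, and 45 of 99 named calls held without each array in turn. With only the arrays compared 47 named calls were lost, and on arrays numbered 2 and 3 alone 65 were lost. The filter on dim genes tested 92 results of named genes again, and none changed its call. It left out named genes with a mean over the 9 arrays at or below 8.022, among them Pdcd1, Cd14 and Mpeg1, so it says nothing about those. Deviations of same-numbered arrays correlated with r of 0.382, -0.128 and 0.4 for FGFR1OP-RET with BCR-ABL and 0.498, -0.152 and 0.41 for the RET fusions. In both, number 2 fell below the limit of 0.1, so these arrays were not treated as pairs, though numbers 1 and 3 exceeded it. Arrays numbered 1 and 3 correlated best with an array of their own number, and those numbered 2 did not. With the fusion in the fit, 887 genes differed between numbers by limma, so an effect of the number over the groups is present. Beyond the calls given in the report, the block changed no call of BCR-RET against BCR-ABL; in FGFR1OP-RET against BCR-ABL it ended those of amino acid stress (0.154) and the unfolded protein response (0.100) and added Bcr (0.0143), and between the RET fusions it added the ERK list (0.0179). Signal over background was not analysed here, so dim genes may be under-called; the filter on dim genes gave 115, 192, 264 and 38.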

Other observations

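Arrays numbered 1 were compared with those numbered 2 and 3 after seeing the data. On the main axis of variation within groups, number 1 stood apart in BCR-ABL and BCR-RET, while FGFR1OP-RET replicate 2 lay on the same side as replicate 1. With the fusion in the fit, 1653 genes differed between number 1 and the others, 565 higher and 1088 lower in number 1, by limma. Among genes chosen after their values were seen, the hypoxia-responsive gene Ankrd37 (1.13), the stress gene Ddit4 (0.84) and the hexokinase gene Hk2 (0.80) were higher on the log2 scale. The basophil protease gene Mcpt8 (-1.10), Ly96 (-1.08) and the granule protease gene Ctsg (-0.85) were lower.

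Of the fixed lists, glycolysis and hypoxia had 7 of 25 genes higher in number 1 and none lower (median 0.10, camera adjusted p = 0.00192). ERK targets had 6 of 24 higher (median 0.08, adjusted p = 0.00228). Cholesterol synthesis had 5 of 19 lower (median -0.16, adjusted p = 1.75e-05), DNA replication 5 of 27 (median -0.08, adjusted p = 0.00192), oxidative phosphorylation 3 of 19 (median -0.11, adjusted p = 0.00276) and lysosome 4 of 21 (median -0.07, adjusted p = 0.0089). Each of these 6 lists had an adjusted p = 0.733 with an estimated correlation. The interferon response list did not differ past the threshold between number 1 and the others (median 0.01, camera adjusted p = 0.934).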
